A study of Mus musculus with 15 samples.

How the data were processed

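Small RNA from mouse epiblast stem cells (EpiSC) derived from Pitx3-GFP mice was measured on 15 single-colour Agilent mouse miRNA arrays, 3 in each of 5 groups. The groups were cells at day 5 before morphogens, treated cells at day 9 and day 14, and control cells at day 9 and day 14. The deposited scanner tables give the spot signals in units of intensity (Cy3), per the file headers from Feature Extraction 11.0.1.1, with no normalization between arrays. Their remaining columns used here, per the file headers, are of another kind (other): flags of 0 or 1 for spots above background, saturated spots and outlier spots. The deposited value table is also in units of intensity: its values are linear, background-subtracted means of each probe's spots with no normalization between arrays, since 73.3% to 83.8% of the probes in 14 of its columns equal the mean of the scanner table within 0.1%. The column medians of that table were 0.100, 0.219 and 0.0453 at day 5, 0.440, 0.542 and 0.381 in treated day 9 cells, 0.700, 0.700 and 0.257 in treated day 14 cells, -0.0215, 0.103 and 0.217 in control day 9 cells, and 0.235, 0.267 and 0.436 in control day 14 cells. In it, the column of treated day 14 replicate 2 repeats that of replicate 1 (86.0% of the probes equal within 0.1%), so these columns were counted as 1 replicate when the table was used as an alternative. The submitters' processing notes name limma 3.20.9 without saying what it was used for.

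The scanner tables were used for all reported values. For each probe the background-subtracted signal was averaged over its spots that were not outliers, divided by the array's 75th percentile over the 353 probes well above background on all 15 arrays, raised to a common floor (-4.27 on the log2 scale) and put on the log2 scale. The floor was the median over arrays of the lowest scaled signal among probes above background. A miRNA was represented by its brightest probe, and of 1122 mouse miRNAs the 306 above background on all arrays of at least 1 group were tested. A probe counted as above background when at least 50% of its spots carried the scanner software's flag. Values at the floor have no order among themselves. Where none of the arrays of a group was above background, the difference is given as "at least" a fold: it was computed against the lowest scaled signal that counted as above background on each of those arrays, or the floor if that was higher. No fold is given where both groups were below background.

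All 5 groups were fitted together in limma 3.58.1 (R 4.3.3, with the data.table package at version 1.17.8 and jsonlite at 2.0.0) with moderated statistics, 10 residual degrees of freedom and 3.06 prior degrees of freedom. Each p is from limma's two-sided test, adjusted by Benjamini-Hochberg over the 306 miRNAs, and called below 0.05; errors given as SE are limma's standard errors. The comparisons were treated against control at day 9 and at day 14, the difference between those 2 (the interaction of treatment and day), and 4 comparisons between days. Simulated data had the day 9 design (20 simulations, 306 miRNAs). In them 100.0% of changes of 2 on the log2 scale were recovered, 97.8% of changes of 1 and 79.8% of decreases of 0.5. Of the calls 3.91% were unchanged miRNAs. The simulated noise was independent between arrays, with no slide difference, scaling or floor, so these shares need not hold for the real calls. Figures were drawn with matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15.

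Fixed before the data were examined were 18 lists of miRNAs: the miR-290 and miR-302 clusters, miR-17-92 with its paralogs, the let-7 family, neuronal miRNAs, neural progenitor miRNAs, the miR-34 and miR-449 family, miRNAs linked to dopaminergic neurons in the literature, the Dlk1-Dio3 and Sfmbt2 clusters, the miR-200 family, the miR-183 cluster, Hox-cluster miRNAs, and markers of striated muscle, mesenchyme and smooth muscle, endothelium and blood, endoderm, and glia. The 13 lists with at least 2 tested members were tested with camera (preset correlation 0.01), adjusted over the lists of a comparison; camera with an estimated correlation and fry, a rotation test of whether members move one way on balance, were alternatives. Camera compares the members of a list with the other miRNAs in the fit, so its p and direction are relative to them. Fry compares the members with 0. No list call held with an estimated correlation. The rule for named miRNAs was also fixed: for treated against control, the 8 with the largest increase and the 8 with the largest decrease among called miRNAs whose 3 arrays of one group all lie above the 3 of the other; 5 and 5 in the other comparisons; up to 4 called members of each list; and always miR-34b, miR-34c, miR-133b, miR-124, miR-9, miR-7a, miR-132, miR-218, miR-302b, miR-294 and let-7c in treated against control.

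The arrays lie on 2 slides. Slide 1 holds the 3 day 5 arrays, the 3 treated day 9 arrays and treated day 14 replicates 1 and 2; slide 2 holds treated day 14 replicate 3 and all control arrays. Slide was not a term of the fit but an alternative, as a fixed block or a random block; the fixed block rests on 1 array, treated day 14 replicate 3, which shares a group with arrays of the other slide. The other alternatives were normexp background correction with offset 50, the total signal per miRNA from the scanner software, the 75th percentile over all probes, quantile normalization, median scaling, a floor 4 times higher, the mean over all probes of a miRNA, no filter on dim miRNAs, a filter for signal on all 15 arrays, the replicate number as a block, only the compared groups in the fit, a trended and robust variance, the deposited value table, and each array left out in turn. The mean spot signal planned for normexp is not among the columns, so the median spot signal and median background were used. The array design names mouse build mm9 while the annotation used here is of another build, so no coordinates are given, and the annotation was used only to find neighbouring miRNA genes.

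The labels do not say that replicates are separate cultures, so the p-values measure the spread between these samples, which may be technical. A permutation test of 3 arrays against 3 cannot give an exact p below 0.1, and the number of arrays limits the precision.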

Results

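The study followed miRNAs while mouse epiblast stem cells, derived from mice that carry a GFP reporter of the dopaminergic neuron gene Pitx3, differentiated over 14 days. From day 5, treated cells received SHH and FGF8, morphogens that pattern the ventral midbrain, and control cells did not. Each of the 5 groups (day 5, treated and control at day 9, treated and control at day 14) had 3 arrays. The 75th percentile of signal used for scaling ran from 149 to 337 intensity units, and 238 to 333 of the 1122 mouse miRNAs were above background per array. Outlier spots made up 3.88% to 5.09% of spots, and 0 spots were saturated. Within groups, replicates correlated at 0.980 to 0.998 (Pearson, log2, across the 306 tested miRNAs, which are not independent replicates). Spike-in controls were lower on slide 2 than on slide 1: the labelling control ran from 2.71 to 2.86 against 2.97 to 3.11 (log10), and the hybridisation control from 4.02 to 4.24 against 4.40 to 4.43.

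The first comparison asked which miRNAs differed between cells with and without morphogens at day 9. Treated cells had more miR-375-3p, miR-34b-5p, miR-34c-5p, miR-27a-3p, miR-29a-3p, miR-132-3p and miR-212-3p, and less of the let-7 family, miR-124-3p and both arms of miR-9. miR-375-3p, best known from endocrine cells, was at -0.53 ± 0.08 (scaled log2 signal, mean ± SD, n = 3) in treated cells and below background in controls, so it was at least 12.6-fold higher (adjusted p = 3.9e-14, limma). miR-34c-5p and miR-34b-5p, transcribed together and known as targets of p53, rose by 1.90 (SE 0.11, adjusted p = 5.2e-09) and 1.88 (SE 0.12, adjusted p = 1.6e-08) on the log2 scale. Among the largest decreases, let-7c-5p fell by 1.08 (SE 0.11, adjusted p = 1.9e-06) and miR-124-3p, abundant in neurons, fell by 0.97 (SE 0.07, adjusted p = 5.6e-08).

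The other large increases at day 9 were miR-27a-3p by 2.48 (SE 0.08, controls above background on 2 of 3 arrays), miR-212-3p by 2.42 (SE 0.26), miR-29a-3p by 2.37 (SE 0.09, controls above background on 2 of 3 arrays), miR-132-3p by 2.27 (SE 0.12), miR-674-3p by 2.12 (SE 0.12) and miR-5097 by 2.01 (SE 0.23). With slide as a block miR-212-3p rose by 1.33 (adjusted p = 0.0089) and each of the other 5 by 1.62 or more. miR-29b-3p, a regulator of extracellular matrix genes like miR-29a-3p, was at least 4.63-fold higher and below background in controls. The other large decreases were miR-137-3p by a log2 change of -1.33 (treated cells above background on 1 of 3 arrays), let-7i-5p by -1.14, miR-9-3p by -1.03, let-7a-5p by -0.88, miR-5622-3p by -0.86 and miR-9-5p by -0.76 (SE 0.07 to 0.15).

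Of the neuronal list, 4 of 16 tested members rose and 6 fell at day 9 (camera adjusted p = 0.0903, direction down). The 4 were miR-212-3p and miR-132-3p, which neuronal activity induces, miR-7a-5p by 0.99 (SE 0.12) and miR-218-5p, known from motor neurons and midbrain, by 0.90 (SE 0.10). Those that fell included miR-137-3p, both arms of miR-9 and miR-124-3p. The list's median was -0.03 and its mean 0.11, so these differ in sign. Camera's direction down, here and for the lists below, means below the other miRNAs, and the median of all 306 was 0.25. In the let-7 family, which rises as stem cells differentiate, 8 of 9 members fell and 0 rose, 5 with slide as a block (median -0.64, and between -1.23 and -0.65 with 4 other scalings; camera adjusted p = 2.2e-06, and adjusted p = 0.45 with an estimated correlation). Of 13 neural progenitor miRNAs 1 rose and 5 fell (median -0.05; camera adjusted p = 0.0334, and adjusted p = 0.454 with an estimated correlation). With slide as a block 1 rose and 3 fell, and the list was not called (adjusted p = 0.0780). The riser was miR-135a-5p, linked to midbrain patterning, by 1.26 (SE 0.15; 0.74 with slide as a block), and miR-181b-5p, miR-181d-5p and miR-181a-5p changed by -0.66, -0.59 and -0.55 (SE 0.07 to 0.09).

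Of 9 miRNAs linked to dopaminergic neurons in the literature, 5 rose and 2 fell at day 9 (camera adjusted p = 0.596), and the list's median of 0.30 turned to -0.01 under another scaling. miR-132-3p, miR-135a-5p, miR-7a-5p and miR-218-5p were among the 5, and miR-181a-5p among the 2. Most members of this list are shared with other lists, so its results are not separate from theirs. miR-7a-5p, miR-7b-5p, miR-132-3p and miR-218-5p are also neuronal members, and miR-125b-5p, miR-135a-5p and miR-181a-5p neural progenitor members. miR-133b-3p, described in midbrain dopaminergic neurons, was above background on 0 of 15 arrays. Both tested members of the miR-34 and miR-449 family, miR-34b-5p and miR-34c-5p, rose (camera adjusted p = 0.0788); the study is known for work on this pair, so the list is not independent evidence. In the Sfmbt2 cluster, a family of near-identical miRNAs that share probe signal, 14 of 31 members rose and 0 fell, beside 124 of 306 miRNAs that rose in all (median 0.62, camera adjusted p = 0.0836). In the same cluster 5 to 11 rose with 4 other scalings (median 0.05 to 0.64) and 7 with slide as a block (median 0.29). miR-467a-5p and miR-467b-5p, for example, rose by 0.98 (SE 0.06) and 0.92 (SE 0.07). Beside them, the 4 viral miRNAs that were above background on all arrays had a median shift of 0.53.

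Few miRNAs of undifferentiated cells were called at day 9. Of the miR-302 cluster, a mark of primed pluripotency, 0 of 5 members were called and miR-302d-3p differed by 0.36 (SE 0.16, adjusted p = 0.075). Of the miR-290 cluster, a mark of naive pluripotency, 1 of 2 was called, miR-290-5p at 0.54 (SE 0.15; adjusted p = 0.33 with slide as a block), while miR-294-3p was not (adjusted p = 0.99); miR-302b-3p was below background in both groups. Of 17 members of miR-17-92 and its paralogs, which promote proliferation, 4 were higher and 1 lower (camera adjusted p = 0.596). With slide as a block 0 were called higher and 0 lower. Among the 4 were miR-20a-3p, miR-106b-3p and miR-25-3p at 0.35 to 0.38, and each turned negative under the all-probe percentile. In the Dlk1-Dio3 imprinted cluster 110 miRNAs are on the array, 12 were above background on any array and 7 were tested. Among the 7, 1 was called, miR-487b-3p, at least 1.43-fold higher (adjusted p = 0.39 with slide as a block). Medians of these 4 lists changed sign under other scalings.

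Among marker miRNAs of other cell types at day 9, both tested mesenchymal miRNAs rose (camera adjusted p = 0.169), miR-21-5p by 1.05 (SE 0.12) and miR-199a-3p by at least 1.57-fold, and so did both glial miRNAs (camera adjusted p = 0.169), miR-219-5p by 1.34 (SE 0.11) and miR-338-3p by 0.63 (SE 0.10; adjusted p = 0.056 with slide as a block). Of 2 endoderm markers, miR-375-3p rose and miR-216a-5p was at least 1.14-fold lower (camera adjusted p = 0.769; miR-216a-5p adjusted p = 0.10 with slide as a block). The mesenchymal list has 11 miRNAs on the array, of which 4 were above background on any array. Both arms of miR-143, miR-145 and miR-214 were above background on 0 arrays. In the endoderm list 3 of 15 were above background on any array, and miR-122, miR-192, miR-194, miR-215 and miR-217 on 0. The tested members therefore do not stand for these lists. The miR-200, Hox-cluster, striated muscle, and endothelium and blood lists had 0 members above background on any array, and the miR-183 cluster had 1 member above background on 1 array. For the 13 tested lists the counts adjusted over the list alone were the same as those over all miRNAs.

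In all, 170 of 306 miRNAs differed at day 9, 124 higher and 46 lower in treated cells, and 29 of the calls were over 2-fold; without adjustment 181 passed. The groups did not overlap for 218 miRNAs (71.2%, against 10% by chance). This split depends on scaling: the median of all miRNAs was 0.25 here, -0.25 with the all-probe percentile (41 of 162 calls higher), -0.03 with quantile normalization (65 of 154) and 0.01 with median scaling (71 of 156). All treated day 9 arrays are on slide 1 and all controls on slide 2, so no within-slide value exists; with slide as a fixed block 75 were called (56 higher), 72 of them shared, and the calls of let-7a-5p, let-7b-5p and let-7e-5p ended. With normexp background the calls of the dim miRNAs miR-137-3p, let-7b-5p, miR-290-5p, miR-199a-3p and miR-338-3p ended.

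**Figure D1:**
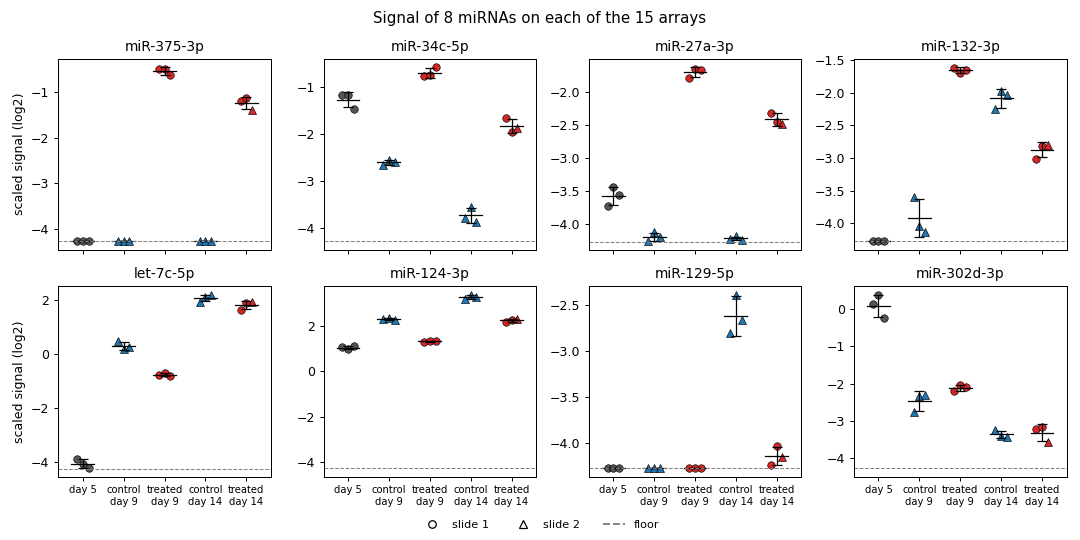
Scaled log2 signal (y axis) of 8 miRNAs on each of the 15 arrays by group (x axis), circles for slide 1 and triangles for slide 2, bars for mean ± SD (n = 3), and the dashed line for the floor. miR-375-3p sits at the floor in day 5 and control cells and at -0.53 and -1.24 on average in treated cells at day 9 and day 14.

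The second comparison asked the same question at day 14. miR-375-3p was still at least 7.90-fold higher in treated cells (-1.24 ± 0.14, SD, n = 3; controls below background; adjusted p = 5.9e-13), and miR-34b-5p and miR-34c-5p rose by 1.90 (SE 0.12, adjusted p = 2.1e-08) and 1.89 (SE 0.11, adjusted p = 8.3e-09). Among the lower miRNAs, miR-129-1-3p fell by 1.78 (SE 0.09, adjusted p = 1.7e-09), miR-129-5p by 1.52 (SE 0.09), miR-124-3p by 1.04 (SE 0.07, adjusted p = 3.7e-08) and miR-9-3p by 1.05 (SE 0.13). Further increases were miR-27a-3p by 1.79 (SE 0.08, controls above background on 2 of 3 arrays), miR-152-3p by 1.61 (SE 0.13), miR-370-3p by 1.61 (SE 0.15), miR-23a-3p by 1.51 (SE 0.07) and miR-29a-3p by 1.29 (SE 0.09). Further decreases were miR-138-5p at -0.94, miR-129-2-3p at -0.84, miR-128-3p at -0.82 and miR-188-5p at -0.80 (SE at most 0.15). With a floor 4 times higher the calls of miR-27a-3p, miR-152-3p, miR-129-5p and miR-138-5p ended.

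Of 16 neuronal miRNAs 11 fell and 2 rose at day 14 (median -0.38; camera adjusted p = 1.5e-05, and adjusted p = 0.498 with an estimated correlation). Besides miR-129-5p, miR-124-3p, miR-9-3p, miR-138-5p and miR-128-3p, named above, miR-132-3p changed by -0.79 (SE 0.12) and miR-9-5p by -0.40 (SE 0.11). miR-129-1-3p and miR-129-2-3p are not on the list. The pair that rose was miR-218-5p, by 1.27 (SE 0.10), and miR-212-3p, by 1.23 (SE 0.26), which was not called with slide as a block (0.50, adjusted p = 0.15). In the let-7 family 5 of 9 fell and 0 rose, 3 with slide as a block (median -0.27; camera adjusted p = 0.0021, and adjusted p = 0.498 with an estimated correlation), led by let-7i-5p at -0.61 and let-7g-5p at -0.54 (SE 0.08 to 0.09). let-7c-5p differed by only -0.27 (adjusted p = 0.048; 0.47 with slide as a block) and was not called without treated replicate 1 or 2 or control replicate 2 or 3 (adjusted p from 0.0624 to 0.209). Both miR-34 members were higher (camera adjusted p = 0.0468, and adjusted p = 0.498 with an estimated correlation), again not independent evidence. Of 13 neural progenitor miRNAs 5 rose and 5 fell (5 and 6 adjusted over the list alone, camera adjusted p = 0.175). With slide as a block 3 rose and 3 fell. Without that block miR-92b-3p rose by 1.05 and miR-99b-5p by 0.52, while miR-135b-5p and miR-181a-5p changed by -0.53 and -0.43.

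Of the miRNAs linked to dopaminergic neurons 2 rose and 3 fell at day 14 (camera adjusted p = 0.295), and the median of 0.01 turned negative under other scalings; miR-218-5p rose and miR-132-3p and miR-181a-5p fell, while miR-7a-5p differed by 0.24 (adjusted p = 0.13). miR-135a-5p rose by 0.67, but not with slide as a block (0.32, adjusted p = 0.19). In the Sfmbt2 cluster 11 of 31 rose and 0 fell (10 adjusted over the list alone; median 0.45; camera adjusted p = 0.175). Its median was 0.11 to 0.55 with 4 other scalings, and 7 rose with slide as a block (median 0.23). Among its members miR-669f-3p rose by 1.07 (SE 0.09) and miR-467b-5p by 1.06 (SE 0.07). The Dlk1-Dio3 members miR-370-3p and miR-494-3p rose, the latter by 1.20 (SE 0.10). The other 5 tested members were not called (camera adjusted p = 0.639), and only 12 of the cluster's 110 miRNAs were above background on any array. The miR-302 and miR-290 clusters had 0 calls among 5 and 2 members. Of 17 members of miR-17-92 and its paralogs 3 were higher and 2 lower (1 and 2 adjusted over the list alone, camera adjusted p = 0.203). With slide as a block 0 of these 17 were called higher and 2 lower. miR-92a-3p changed by -0.54 (SE 0.08). Among markers of other cells, miR-21-5p rose by 0.69 (SE 0.12), miR-199a-3p was at least 1.47-fold higher and miR-219-5p rose by 0.78 (SE 0.11), while miR-338-3p changed by -0.41 (SE 0.10); camera adjusted p was 0.255 for mesenchyme, 0.848 for glia and 0.267 for endoderm.

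In all, 163 miRNAs differed at day 14, 119 higher and 44 lower, 30 of them over 2-fold; without adjustment 178 passed. The groups did not overlap for 171 (55.9%, against 10% by chance). The median of all miRNAs was 0.21 here and -0.08 with the all-probe percentile (37 of 114 calls higher), and 69 of 135 calls were higher with quantile normalization and 76 of 140 with median scaling (median 0.01). With slide as a block 107 were called (73 higher), 104 of them shared, and let-7b-5p was not called. That fit sets treated replicate 3, the lone treated array on slide 2, against the 3 controls. It assumes that the lone array varies like the other groups. A fit within slide 2 gives the same changes (median 0.12 in both), so it is not a separate check.

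The third question was whether the effect of treatment differed between the days. miR-132-3p was above controls at day 9 and below them at day 14, a difference of -3.06 (SE 0.17, adjusted p = 4.5e-08). Its genomic neighbour miR-212-3p was above controls at both days. With slide as a block miR-212-3p was not called at day 14 (0.50, adjusted p = 0.15). miR-129-2-3p turned the same way, from 1.32 to -0.84 (difference -2.16, SE 0.21). These turns are against controls of the same day and need not be turns in treated cells. As given below, both miRNAs rose in controls from day 9 to day 14, and miR-132-3p fell in treated cells. In all, 14 miRNAs were called in opposite directions at day 9 and day 14. For miR-34b-5p and miR-34c-5p the differences were 0.02 (SE 0.17, adjusted p = 0.95) and -0.01 (SE 0.15, adjusted p = 0.97), which does not show that the effects were equal; with a floor 4 times higher both were negative and called. The excess of miR-7a-5p was smaller at day 14 (-0.75, SE 0.18). miR-375-3p and miR-29b-3p were below background in controls at both days, so no size is given for the change of their excess. miR-370-3p and miR-494-3p gained 1.46 (SE 0.21) and 1.01 (SE 0.14). The deficit of let-7c-5p shrank by 0.81 (SE 0.15, adjusted p = 0.0014); 5 of 9 let-7 members changed this way (median 0.44; camera adjusted p = 0.0584). With a floor 4 times higher let-7i-5p, 1 of the 5, turned to -0.54 and was called that way (adjusted p = 0.00061). Of the neuronal list 2 rose and 6 fell (4 and 7 adjusted over the list alone; camera adjusted p = 0.169), and miR-338-3p and miR-219-5p, the glial pair, changed by -1.04 (SE 0.14) and -0.56 (SE 0.15).

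In all, 100 miRNAs differed in their response between the days, 51 up and 49 down (127 without adjustment), and 95 with slide as a block, 91 of them shared. With the all-probe percentile, which moved the median from -0.07 to 0.13, 55 of 80 were up. miRNAs called at both days in the same direction numbered 77 higher and 23 lower, against 48.2 and 6.61 expected if the days were independent. They are not, since at both days the controls are on slide 2 and most treated arrays on slide 1.

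**Figure D2:**
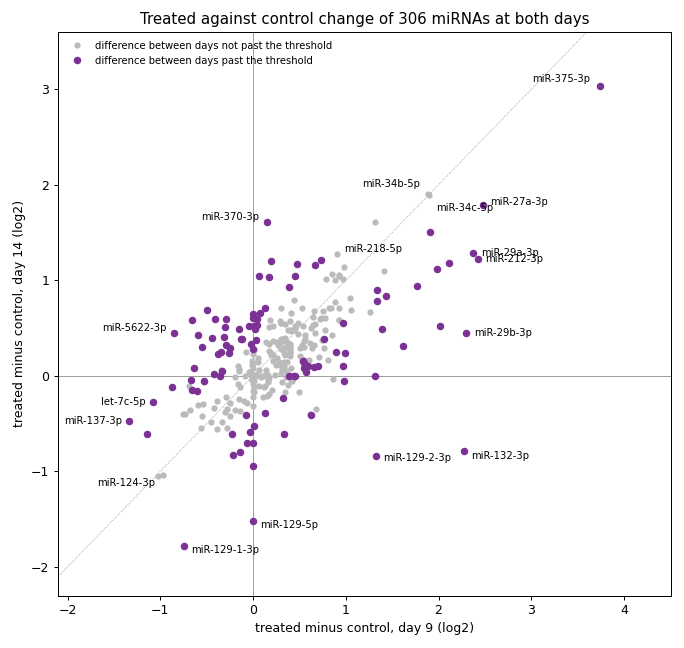
Log2 change of treated against control at day 9 (x axis) and day 14 (y axis) for 306 miRNAs, purple where the change differed between days (100 miRNAs); the dotted line marks equal change. miR-34b-5p and miR-34c-5p lie near that line at 1.9 on both axes, and miR-132-3p moves from 2.27 to -0.79.

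Between day 5 and day 9 of treated cells, on the same slide, markers of primed pluripotency fell and differentiation miRNAs rose. All 5 miR-302 cluster members fell (camera adjusted p = 3.9e-05, and adjusted p = 0.185 with an estimated correlation), miR-302d-3p by 2.20 (SE 0.16) and miR-302a-3p by 2.56 (SE 0.11, above background on 2 of 3 arrays at day 9), and miR-302b-3p was at least 4.03-fold lower. Of miR-17-92 and its paralogs 15 of 17 fell and 0 rose (median -0.92; camera adjusted p = 2.1e-09, and adjusted p = 0.0587 with an estimated correlation), with miR-18b-5p at -2.40 (SE 0.11, above background on 1 of 3 arrays at day 9) and miR-363-3p at -2.01 (SE 0.07). Both miR-290 cluster members fell, miR-294-3p by 1.17 (above background on 1 of 3 arrays at day 9; camera adjusted p = 0.0466, and adjusted p = 0.185 with an estimated correlation). let-7c-5p, let-7a-5p and let-7f-5p rose by 3.27, 3.22 and 2.93 (SE 0.10 to 0.15, above background on 1 or 2 of 3 arrays at day 5) among 8 of 9 let-7 members that rose (median 1.81, or 1.45 with the 5 members below background at day 5 at their bound; camera adjusted p = 0.00051, and adjusted p = 0.222 with an estimated correlation). Of 13 neural progenitor miRNAs 11 rose and 1 fell (camera adjusted p = 0.0011, and adjusted p = 0.222 with an estimated correlation), miR-125b-5p by 2.46 (SE 0.10) and miR-99a-5p by 2.00 (SE 0.06). Of the neuronal list 8 of 16 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.215), and of miRNAs linked to dopaminergic neurons 8 of 9 rose (camera adjusted p = 0.0036, and adjusted p = 0.222 with an estimated correlation). The dopaminergic list shares most of its members with the neuronal and neural progenitor lists, so its call is not separate from theirs. miR-375-3p, miR-29a-3p and miR-132-3p were at least 10.4-fold, 5.12-fold and 4.78-fold higher, and miR-34c-5p and miR-34b-5p rose by 0.56 (SE 0.11) and 0.54 (SE 0.12). Some markers of other cells moved up too. Both tested mesenchymal miRNAs rose (camera adjusted p = 0.170), miR-21-5p by 1.35 (SE 0.12) and miR-199a-3p by at least 1.30-fold. Both tested glial miRNAs rose (camera adjusted p = 0.326), miR-219-5p by 0.58 (SE 0.11) and miR-338-3p by 0.49 (SE 0.10, above background on 2 of 3 arrays at day 5). In all 180 were called, 115 higher and 65 lower, and the share of higher calls fell to 92 of 179 with quantile normalization, 94 of 180 with median scaling and 77 of 157 with the all-probe percentile (median of all miRNAs 0.10 here, -0.02 there).

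In controls over the same days, a comparison wholly across slides, let-7c-5p rose by 4.35 (SE 0.11), let-7a-5p by 4.10 (SE 0.15) and let-7f-5p by 3.53 (SE 0.10). Again 8 of 9 let-7 members rose (median 2.45, or 2.09 with 5 members at their bound; camera adjusted p = 1.1e-07, and adjusted p = 0.103 with an estimated correlation). Of neural progenitor miRNAs 10 of 13 rose and 1 fell (camera adjusted p = 2.2e-06, and adjusted p = 0.103 with an estimated correlation), led by miR-125b-5p at 2.76 (SE 0.10). miR-9-3p, miR-9-5p and miR-124-3p rose by 2.36, 2.30 and 1.25 (SE 0.07 to 0.13) among 8 of 16 neuronal miRNAs that rose, while 1 fell (camera adjusted p = 0.0146, and adjusted p = 0.483 with an estimated correlation). The one that fell was miR-212-3p, by 1.97 (SE 0.26), or by 0.88 with slide as a block (adjusted p = 0.056). All 5 miR-302 members fell (camera adjusted p = 0.00044, and adjusted p = 0.185 with an estimated correlation), miR-302a-3p by 2.71 (SE 0.11), and 16 of 17 in miR-17-92 and its paralogs (camera adjusted p = 1.0e-06, and adjusted p = 0.103 with an estimated correlation). In contrast to treated cells, miR-34b-5p and miR-34c-5p fell, by 1.34 (SE 0.12) and 1.33 (SE 0.11). Of 180 calls 73 were higher and 107 lower; the split was 107 of 156 higher with the all-probe percentile, 98 of 179 with quantile normalization and 51 of 98 with slide as a block. The median of all miRNAs was -0.09 here, 0.18 with the all-probe percentile and -0.21 with the total signal.

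From day 9 to day 14 in treated cells, miR-137-3p, a neuronal miRNA, rose by 2.88 (SE 0.13, above background on 1 of 3 arrays at day 9), and let-7b-5p, let-7c-5p, let-7i-5p and let-7a-5p by 2.64, 2.57, 2.15 and 2.09 (SE 0.09 to 0.15). Of the let-7 family 8 of 9 rose (median 1.88; camera adjusted p = 2.3e-05, and adjusted p = 0.367 with an estimated correlation), of neural progenitor miRNAs 9 of 13 (camera adjusted p = 0.0195, and adjusted p = 0.40 with an estimated correlation) and of neuronal miRNAs 10 of 16, while 2 fell (camera adjusted p = 0.0684). The neuronal pair that fell was miR-132-3p by 1.22 (SE 0.12) and miR-212-3p by 1.18 (SE 0.26). Of miR-17-92 and its paralogs 14 of 17 fell (camera adjusted p = 1.9e-06, and adjusted p = 0.185 with an estimated correlation), miR-18a-5p by 1.59 (SE 0.11) and miR-92a-3p by 1.45 (SE 0.08). miR-29b-3p fell by 1.85 (SE 0.12), miR-34c-5p by 1.13 (SE 0.11), miR-34b-5p by 1.1 (SE 0.12), miR-219-5p by 0.94 (SE 0.11) and miR-375-3p by 0.70 (SE 0.07). Of the Sfmbt2 cluster 10 of 31 fell and 0 rose (8 adjusted over the list alone; camera adjusted p = 0.0894). In all 202 were called, 108 higher and 94 lower, and 86 of 205 were higher with median scaling, which moved the median of all miRNAs from 0.01 to -0.14 (-0.10 with the total signal).

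In controls from day 9 to day 14, within slide 2, the neuronal list moved up: 14 of 16 members rose and 1 fell (median 0.92; camera adjusted p = 0.00017, and adjusted p = 0.340 with an estimated correlation). Among its members miR-137-3p rose by 2.02 (SE 0.13) and miR-132-3p by 1.84 (SE 0.12), and miR-129-5p and miR-138-5p were at least 2.96-fold and 2.62-fold higher. miR-129-2-3p, which is not on that list, rose by 2.14 (SE 0.15). All 9 let-7 members rose (median 1.44; camera adjusted p = 3.6e-05, and adjusted p = 0.266 with an estimated correlation), let-7b-5p by 2.31 (SE 0.11). Of the miRNAs linked to dopaminergic neurons 7 of 9 rose (camera adjusted p = 0.0031, and adjusted p = 0.266 with an estimated correlation), miR-7a-5p by 1.33 (SE 0.12). Again, most members of this list are also in the neuronal or neural progenitor list. Of miR-17-92 and its paralogs 13 of 17 fell (camera adjusted p = 7.5e-08, and adjusted p = 0.105 with an estimated correlation), miR-18a-5p by 1.66 (SE 0.11) and miR-363-3p by 1.56 (SE 0.07). miR-34b-5p and miR-34c-5p fell by 1.12 each (SE 0.12 and 0.11), calls that ended with a floor 4 times higher. For their list camera adjusted p was 0.0457, and adjusted p = 0.266 with an estimated correlation. Among markers of other cells, list medians were -0.16 for mesenchyme, -0.18 for endoderm and 0.22 for glia, with 2 tested members each. In all 166 were called, 96 higher and 70 lower; 66 of 180 were higher with median scaling (median of all miRNAs -0.10 against 0.06 here), 70 of 160 with the all-probe percentile, 80 of 173 with quantile normalization and 71 of 161 with the total signal.

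**Figure D3:**
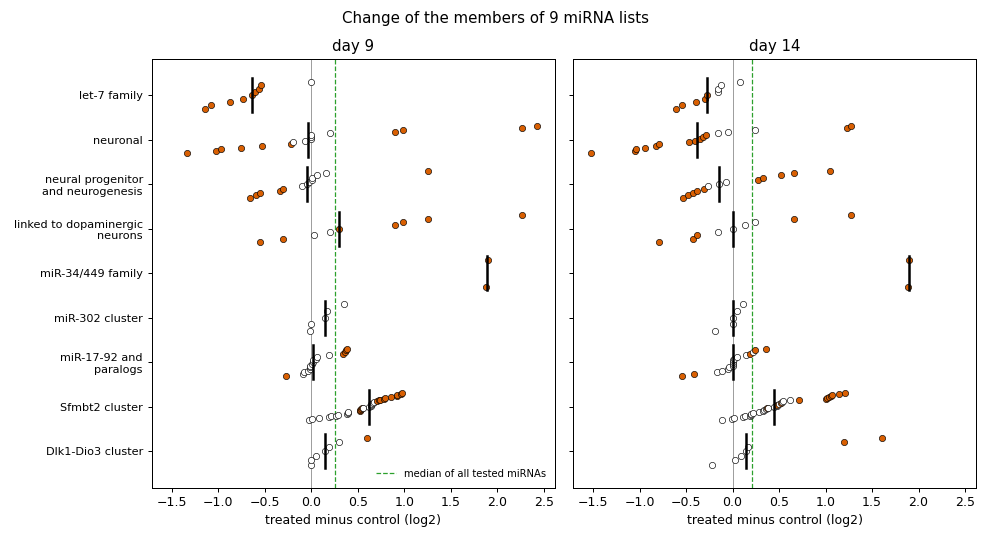
Log2 change of treated against control for the tested members of 9 lists at day 9 (left) and day 14 (right), filled orange where called, with each list's median as a black bar and the median of all 306 miRNAs (0.25 and 0.21) as a dashed line. In the let-7 family 8 of 9 members fell at day 9 and 5 at day 14, and the medians of the miR-302, miR-17-92, dopaminergic and Dlk1-Dio3 lists change sign at day 9 under other scalings.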

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

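Chosen only after the result was seen were the tests of the let-7 family against scaling and a delay, and the slide test of the Sfmbt2 cluster. The other tests below were set before it. The intervals given in this part come from resampling miRNAs, which are not independent replicates. They do not measure the spread between arrays or cultures.

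The effect of treatment differed between day 9 and day 14 for 100 miRNAs, by a test of the difference itself. The difference (day 14 minus day 9, log2) was 1.46 for miR-370-3p, 1.30 for miR-5622-3p, 1.24 for miR-5105, 1.19 for miR-5109, 1.02 for miR-1306-3p and 0.81 for let-7c-5p. It was -3.06 for miR-132-3p, -2.16 for miR-129-2-3p, -1.85 for miR-29b-3p, -1.52 for miR-129-5p, -1.49 for miR-5097 and -0.75 for miR-7a-5p. miR-29b-3p was below background in controls at both days and miR-129-5p in both groups at day 9, so their values hold differences from the floor and are not sizes of the change. Of 100 splits of treated and control labels drawn within each day, 2 gave as many, the real split (100) among them, and the highest of the others gave 110. That split kept the day 9 groups whole but turned round, and mixed 1 array of each group at day 14. Such splits also break up the treatment effect that the days share, so they do not show what the difference between days would be by chance, and nothing is concluded from them. For the 6 comparisons of groups, 10 splits are too few for a share under 0.05: the real split gave 170 and 163 miRNAs for treated against control at day 9 and day 14, 180 and 202 for treated cells up to day 9 and from there to day 14, and 180 and 166 for controls over the same spans, and the highest other split gave 0 in each, so 1 split of 10 was as large.

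Of 57 viral miRNAs with probes on the arrays, outside the mouse miRNAs of the report, 7 were above background on any array and 4 on all 15. Among these 4, mcmv-miR-m88-1 was higher in treated than in control cells by 0.85 at day 9 and 1.00 at day 14 with groups that did not overlap, and mghv-miR-M1-2-3p and mcmv-miR-M23-1-5p by 0.78 and 0.29 at day 9. No group had 4 or more arrays, so no array was compared with its own group for distance.

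The first pattern weighed is the number of miRNAs called between treated and control cells, since all control arrays are on slide 2 and all but 1 treated array on slide 1. In treated cells at day 14, the only group on both slides, the slide difference signed by the call had a median of 0.194 of the median call at day 9 (95% interval 0.147 to 0.236) and 0.120 at day 14 (0.0446 to 0.192). Both shares are under the 0.5 set beforehand, but they rest on 1 array on slide 2, so slide and treatment cannot be told apart by this test, and the effect of treatment and the slide stay open. With slide as a block 72 and 104 of the calls passed as well, among them miR-375-3p, miR-34b-5p and miR-34c-5p at both days.

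The next pattern is the lower let-7 family in treated cells at day 9, where scaling as the cause is argued against: the family's median closest to 0 over 4 other scalings was -0.65. For 8 of 9 members the treated day 9 mean lay between day 5 and control day 9, but this says nothing for or against treated cultures running behind the controls, since the lower level than in controls and the rise from day 5, where most members lie at the floor, were already known. Of the 170 miRNAs called at day 9, 48.2% (95% interval 41.2% to 55.9%) lay above both or below both of day 5 and control day 9. With other scalings the share was 44.5% to 51.9%. Which side depends on scaling: 72 above and 10 below here, but 31 and 46 with the all-probe percentile. A delay would forbid such values only if controls moved in a single direction between those days, and no control was sampled between them. Treated day 9 and control arrays also lie on different slides. The test therefore cannot decide whether a delay is the whole cause of the day 9 difference. The change at day 9 correlated at -0.150 (95% interval -0.311 to 0.0156) with the change from day 5 to treated day 14, which leaves a delay open there. The change at day 14 correlated at 0.179 (0.0178 to 0.345, Spearman 0.0988) with the change from day 5 to treated day 9. Cultures behind at day 14 could lag on the later change rather than on this early one, so nothing is concluded from that value. For let-7 and for the other called miRNAs a delay and a direct effect of the morphogens stay open.

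The last pattern is the 14 of 31 members of the Sfmbt2 cluster called higher in treated cells at day 9, against 124 of 306 miRNAs in all. The cluster's median was 0.62 (0.05 to 0.64 with 4 other scalings, 0.29 with slide as a block), and camera did not call it as a group (adjusted p = 0.0836; 0.132 with slide as a block, 0.579 with an estimated correlation). If unspecific binding or background differed between the arrays, viral miRNAs would shift by at least 0.5 of the cluster's median, 0.312. The 4 viral miRNAs above background on all arrays had a median shift of 0.534, but their interval, -0.167 to 0.845, holds both outcomes. The cluster differed by 0.127 between slides in treated day 14 cells, under 0.5 of its shift, but again from 1 array on slide 2. Unspecific binding, the slide and a change of the cluster in treated cells therefore cannot be told apart, and the near-identical members share probe signal.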

How the results depend on the processing

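The counts of miRNAs passing with and without slide as a block, and the counts limited to miRNAs above background in all compared arrays, were chosen after seeing the data. Log2 changes are given unless an adjusted p is named, and comparisons carry the names treated (T) and control (C) with the day.

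Of 7 counts, none moved beyond 1.5-fold with the authors' value table, other scalings, no filter, slide as a random block or a replicate block. The same held with compared groups only, the mean of all probes, and trend and robust limma. A similar count does not mean the same miRNAs. With the all-probe percentile 90 of the 170 T9 against C9 calls were shared, whatever their sign, and 81 of the 163 T14 against C14 calls. With quantile normalization 108 and 109 were shared. Slide as a random block could change little, since the estimated correlation of arrays on a slide was 0.0113. With normexp background the counts fell to 83 (T9 against C9), 70 (T14 against C14), 106 (T9 against day 5), 133 (T14 against T9), 112 (C9 against day 5), 96 (C14 against C9) and 37 (difference between days). With a floor 4 times higher they were 95, 93, 133, 108 and 96 for T9 against C9, T14 against C14, T14 against T9, C9 against day 5 and C14 against C9. Both settings shrink changes near background by construction. Testing only miRNAs above background on all arrays left fewer miRNAs and counts of 105 (T9 against C9), 118 (T9 against day 5) and 58 (difference between days). With slide as a fixed block the counts were 75 (T9 against C9, 72 passing both), 107 (T14 against C14, 104 passing both) and 98 (C9 against day 5). A fit within 1 slide (T14 against C14) rests on the same lone treated array and gives the same changes, so it is not a separate check.

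Leaving out 1 array at a time gave 149 to 160, 145 to 165, 163 to 197, 189 to 196, 160 to 183, 150 to 161 and 81 to 110 miRNAs, and 81 leave-one-out values of named miRNAs lost the threshold. The order is T9 against C9, T14 against C14, T9 and T14 in time, C9 and C14 in time, and the difference between days. With a replicate block the counts were 170, 157, 178, 200, 177, 166 and 97; correlations of treated and control residuals of the same number were 0.10, -0.22 and 0.21 at day 9 and -0.06, -0.24 and -0.16 at day 14, which gives no sign that the numbers pair samples.

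Of 284 values of named miRNAs, 60 lost the threshold with normexp, 83 with the higher floor, 33 with slide as a fixed block and 2 to 31 with other settings that tested all of them, bar trend and robust limma with 0. Signs turned as follows. All-probe percentile: T9 against C9 miR-20a-3p -0.14, miR-106b-3p -0.22, miR-17-5p -0.23, miR-25-3p -0.24; T14 against C14 miR-106b-3p -0.0174, miR-93-5p -0.14; C9 against day 5 miR-494-3p 0.11; difference between days miR-20a-3p 0.14, miR-363-3p 0.0646. Quantile: miR-20a-3p -0.10 and miR-106b-3p -0.0915 (T9 against C9), miR-106b-3p -0.00923 (T14 against C14), miR-20a-3p 0.10 (difference). Normexp: miR-106b-3p -0.0448 (T14 against C14), miR-432 -0.11 (T9 against day 5), miR-132-3p -0.10 and miR-216a-5p -0.18 (C9 against day 5), let-7i-5p -0.0665 and miR-466b-3p -0.11 (difference). Higher floor, difference: miR-363-3p 0.0433, let-7i-5p -0.54 (adjusted p = 0.00061), miR-92b-3p -0.0112, miR-34b-5p -1.10 (adjusted p = 0.00028). Median scaling, difference: miR-363-3p 0.0221. Total gene signal, difference: miR-297c-5p 0.58. The authors' table gave miR-487b-3p -2.74 (T9 against C9) and 2.99 (C9 against day 5), from 1 outlying value of control day 9 replicate 1. The all-probe percentile divides each array by another constant, so changes away from the floor shift together, and small ones can turn sign with that shift. It moved the median of all miRNAs from 0.25 to -0.25 (T9 against C9) and from 0.21 to -0.08 (T14 against C14). The shift was from -0.09 to 0.18 for C9 against day 5 and from -0.07 to 0.13 for the difference. For the turns under the remaining settings the cause was not tested.

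Of 91 list results, 24 lost the threshold with an estimated correlation and 44 gained it with fry. Directions turned to up at day 9 without a filter for miR-17-92 (camera adjusted p = 0.0386) and Dlk1-Dio3 (camera adjusted p = 0.0386). They also turned to up with fry for Dlk1-Dio3 (adjusted p = 0.0185), and to down without a filter for Sfmbt2 in the difference (camera adjusted p = 0.0135). In these settings the changes of the members were the same, and what they were compared with differed. Without the filter the median of all miRNAs moved from 0.25 to 0 at day 9 and from -0.07 to 0 in the difference, and fry compares with 0.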

Other observations

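The test of neighbouring miRNA genes was chosen only after the result was seen, and the miRNAs named in this part were chosen after their values were seen.

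Some miRNAs whose genes lie next to each other moved together at day 9, while others did not, such as miR-362-3p at 0.66 and miR-188-5p at -0.15. miR-23a-3p rose by 1.91 in treated cells at day 9 (SE 0.07, adjusted p = 7.5e-11) beside its neighbour miR-27a-3p, and the related pair miR-23b-3p and miR-27b-3p rose by 0.30 and 1.05. miR-674-5p and miR-674-3p, arms of one hairpin, rose by 1.43 and 2.12, and miR-335-5p rose by 0.97 while miR-335-3p was at least 2.35-fold higher. miR-210-3p, induced by low oxygen, rose by 0.88 at day 9 and 0.77 at day 14. Over 35 hairpins with both arms tested, the changes of the arms correlated at 0.773 at day 9 and 0.532 at day 14 (Pearson, across hairpins), and of the 11 with both arms called at day 9, 10 had arms that changed in the same direction.

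A shared primary transcript was tested as a hypothesis on neighbouring miRNAs of different number. Over 28 pairs from 36 miRNAs the mean difference of the day 9 change was 0.317, and 99.9% of 10000 random pairings of the 195 loci had a larger one (98.99% with the 17 pairs above background on all compared arrays). At day 14 the share was 92.5% (83.7% with 16 pairs), where miR-132-3p and miR-212-3p moved apart, at -0.79 and 1.23; the latter was 0.50 with slide as a block. The day 9 value is what shared transcripts could give, but pairs were found and tested on the same data. Pairs in which neither miRNA changed much, such as miR-19a-3p and miR-20a-5p at 0.07 and 0.02, also count as alike. Shared regulation of separate transcripts was not tested.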
